A study of Homo sapiens with 15 samples.

How the data were processed

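RNA was sequenced from cultured cells that had been sorted from human uterine tissue for the surface antigens Stro-1 and CD44, per the labels' protocols. The cells were grown at low oxygen before RNA was extracted. The 15 libraries formed 3 groups of 5: cells from myometrium of uteri without fibroids (MyoN), cells from myometrium next to fibroids (MyoF) and cells from the fibroids themselves (F). Groups were taken from the labels. Each F library shared its donor code with 1 MyoF library, which gave 5 donor pairs, and the MyoN libraries came from other donors. The libraries were deposited in 2 tables, here called library set 1 (3 libraries per group) and library set 2 (2 libraries per group).

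The deposited tables held raw read counts per gene, as whole numbers. The submitters' processing notes name HISAT2, featureCounts, edgeR and the hg38 build, without versions. The strand setting and the annotation release are not given in the sources used here. Both tables listed the same 58735 gene identifiers, and all of them occur in GENCODE release 29 on GRCh38 (hg38), from which positions were taken. Because the strand setting is not given, reads of overlapping antisense genes cannot be told apart. Values are therefore uncertain for named genes whose spans overlap another tested gene: CNP, PDZD7, RN7SL4P, CCNA2, P4HA2, MFAP4, ACAT2, KRT8, KRT18, KRT7, EGLN3, DDIT3, ENO2, RPS13, HOXA7, HOXA9, MT-ND4L and MT-ATP8. Reads of ribosomal protein genes, mitochondrially encoded genes and HSPA1B can also be shared with pseudogenes or near-identical copies.

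Total counts per library ran from 6475038 to 16696450 in set 1 and from 5143548 to 9111931 in set 2. As a check for a library deposited more than once, libraries of a group were compared over genes, and the chi-square per degree of freedom was between 18.7 and 138, so no 2 were alike within sampling noise. The biological coefficient of variation was 0.333. With 1 culture per donor and tissue, donor and culture cannot be separated in it.

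Counts were tested with edgeR 4.0.16 in R 4.3.3, using TMM scaling, the filterByExpr filter and the robust quasi-likelihood F test. All 15 libraries entered a single fit with a term for group and a term for library set. It treated F and MyoF libraries of a donor as independent. Genes on the Y chromosome and XIST (519 identifiers) were left out, and 14024 genes passed the filter. P-values were adjusted by the Benjamini-Hochberg method, and genes under 0.05 were called. The standard error of a log2 fold change was taken as its size divided by the square root of F. Levels are CPM, the count scaled to a fixed library total, with SD over 5 libraries, computed from the deposited counts. Log2 CPM used a prior count of 2.

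Before the data were examined, 43 gene lists with 995 memberships were written, of which 41 had at least 5 tested members. They were tested with camera in limma 3.58.1 at a preset correlation of 0.01, two-sided, with adjustment over 123 tests, and again with the correlation estimated from the data. Chosen after the data were seen, the mean log2 CPM of each list was also compared between groups by a two-sided exact permutation test over 252 labellings, where the smallest possible p is 0.00794, or over 32 swaps within donor pairs, where it is 0.0625. The p from labellings was also adjusted over 123 tests, where a list could pass only if many reached the smallest p together. Failure after that adjustment is therefore no evidence against a difference. The leukocyte list (0 of 16 members tested) and the adipocyte list (4 of 13) were not tested.

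The genes named were set by a rule written before the data were examined: called genes of at least 1 CPM with the same sign in both sets, up to 8 each way by fold; the 5 with the smallest p where fewer than 5 were called; CD44; and up to 4 members of each list with the smallest adjusted p. Of the last part, the text gives the 2 members with the smallest p for lists that passed camera; that narrowing was set after values had been seen. A few of the genes so chosen are not reported here, but they still count in the list results. Genes whose presence commonly differs between people were not named.

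F and MyoF libraries of a donor deviated together. The correlation of their residuals was 0.37 on average and ran from 0.08 to 0.66, over 0.1 in 4 of 5 pairs. The pairing itself comes from the donor codes in the labels, and a fit with the donor as a block was the alternative set for F against MyoF before the data were examined.

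The procedure was tested on simulated counts with the real means, dispersions and library sizes, of 14024 genes, some of them changed by known folds. For MyoF against MyoN it recovered 12.5% of changes of 1.5-fold, 48.3% of 2-fold and 75.7% of 4-fold. For F against MyoN the shares were 8.06%, 47.1% and 80.0%, and for F against MyoF 10.9%, 47.2% and 82.8%. False calls numbered 0, 1 and 2. With the donor block for F against MyoF the shares were 0%, 27.8% and 68.8%, with 5 false calls. The simulation held no donor effects, which a block could remove, and no difference by donor code format. Its shares are therefore not the power in the real data. For F against MyoN, UPK1B, MCTP2 and IFI6 had log2 fold changes of -5.28, -3.79 and -3.20 and were not called (edgeR adjusted p = 0.279 for each). A count of 0 calls thus does not show that large changes are absent. In MyoN these 3 genes were widely spread, at 19.1 ± 14.8, 8.82 ± 7.53 and 113 ± 97.1 CPM (SD). IFI6 is in the interferon list, whose median log2 fold change was -1.96, and -0.36 with donors of 1 code format only. It is therefore not shown that these differences go with fibroids.

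Alternatives were other scalings and filters, DESeq2 1.42.0, limma voom, fits without the set term, on each set or on 2 groups, the donor block, and leaving out each library in turn. Those chosen after the data were seen were a term for the format of the donor code, fits on donors with the prefixed format, sample weights, the division of donor pairs for the fold-change correlation, and the lists with a library left out. The donor codes have 2 formats in the labels: 3 MyoN donors have an unprefixed code, and the other 2 MyoN donors and every MyoF and F donor have a prefixed code. The term for the format and the fits on prefixed donors therefore both set MyoF and F against the same 2 MyoN libraries. They are not independent checks.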

Results

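Transcripts were counted in 15 cultures of Stro-1+/CD44+ cells, a surface phenotype used to enrich stem-like cells of the myometrium, the muscle layer of the uterus. The cultures came from myometrium without fibroids (MyoN, n = 5), myometrium adjacent to fibroids (MyoF, n = 5) and fibroids (F, n = 5), which are benign smooth muscle tumours. MyoF and F were paired by donor. Library totals were between 5143548 and 16696450 counts, 21949 to 30578 genes had at least 1 count, and mitochondrially encoded genes took 1.57 to 3.30% of counts. On the first principal component of log2 CPM (22.1% of variance), libraries of set 1 lay between -45.1 and 14.9 and those of set 2 between -6.23 and 51.8. On the second (18.5%), the 3 MyoN libraries with unprefixed donor codes lay at 40.7, 51.8 and 55.6, and the other 12 libraries at 17.8 or below.

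**Figure D1:**
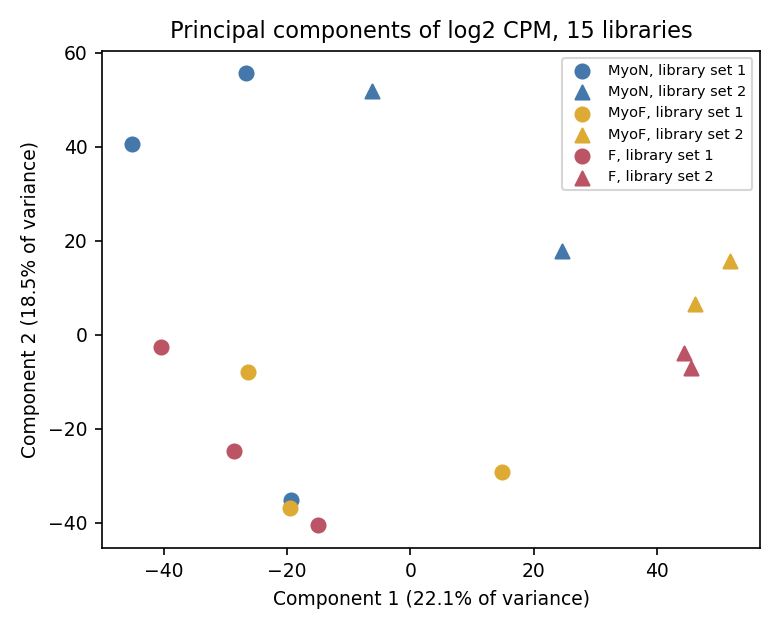
Each point is 1 library, placed by its first 2 principal components of log2 CPM (axes in component units, with the share of variance in percent). Colour gives the group and shape the library set; 3 MyoN libraries lie above 40 on component 2, apart from the rest.

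The first comparison asked how cells of myometrium next to fibroids differed from cells of fibroid-free myometrium. TRIB3, a pseudokinase induced by the integrated stress response, was 3.13-fold higher in MyoF, at 53.5 ± 36.3 CPM (SD, n = 5) against 15.5 ± 5.31 in MyoN. MXI1, a MYC antagonist that is also induced by hypoxia, was 1.70-fold higher, at 123 ± 20.6 against 72.6 ± 15.3 CPM. TRIB3 (ENSG00000101255) lies on chromosome 20 from 362835 to 397559 and MXI1 (ENSG00000119950) on chromosome 10 from 110207605 to 110287365, both on the plus strand. They were the 2 genes of 14024 that passed edgeR's test, with log2 fold changes of 1.65 ± 0.22 and 0.77 ± 0.11 (SE) and an adjusted p of 0.0471 for each. The fit treated the F libraries as independent of the MyoF libraries of the same donors, so these SE and p may be too small. An unadjusted p under 0.05 was found for 1512 genes, where 701 would be expected with no difference. This count was 602 with a term for the donor code format, and 807 of 14993 genes among prefixed donors. Both of these fits rest on 2 MyoN libraries. In the main fit the next 3 genes by p did not pass (adjusted p = 0.156): COL6A2, a collagen VI chain, with a log2 fold change of 1.33 ± 0.23, GNPTAB with -0.77 ± 0.13 and MAMLD1 with 1.65 ± 0.29. CD44, the sort antigen, was at 1059 ± 540 CPM in MyoF and 1126 ± 381 in MyoN (adjusted p = 0.954).

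**Figure D2:**
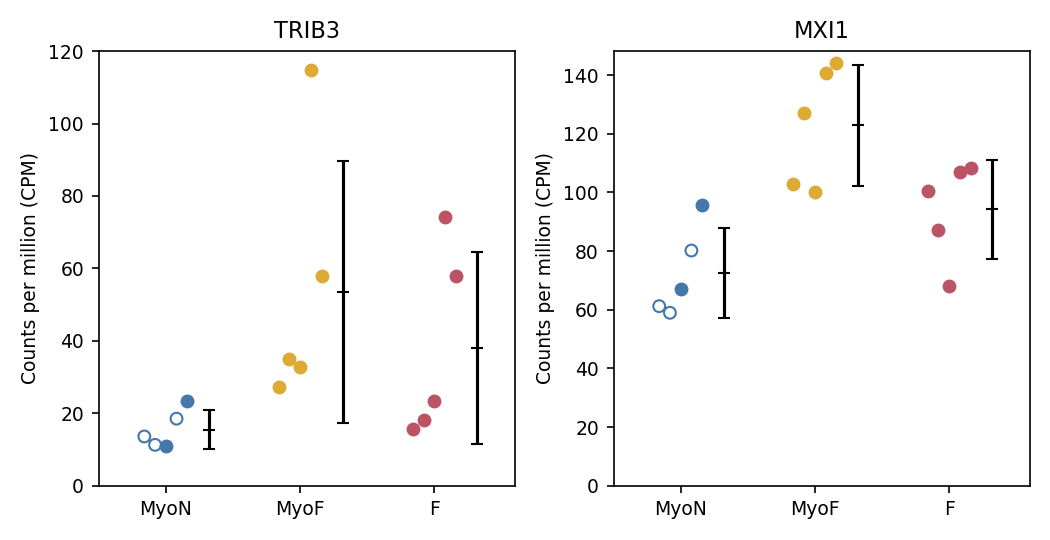
CPM of TRIB3 and MXI1 in each library, by group; open points are MyoN libraries with unprefixed donor codes, and the bar beside each group is the mean with its SD (n = 5). MyoF averaged 53.5 CPM for TRIB3 and 123 CPM for MXI1, against 15.5 and 72.6 in MyoN.

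The calls of TRIB3 and MXI1 were close to the threshold. They ended with RLE scaling (adjusted p = 0.0546 for both), without the set term, and with the 2 groups alone (0.144 for both). A donor correlation of 0.479 in limma voom also ended them (0.0518 for both, against 0.0414 without it). So did a term for the donor code format, although the log2 fold change then was still 1.71 for TRIB3 and 0.64 for MXI1. Within library set 1 the fit called 1 gene and within set 2 it called 2, none of them TRIB3 or MXI1, whose log2 fold changes were 1.42 and 0.82 in set 1 and 2.04 and 0.69 in set 2. With 1 library left out, both calls held only without MyoN replicate 3, MyoN replicate 5 or F replicate 1. Those 2 MyoN libraries are the ones with prefixed donor codes. Without F replicate 3 the call of TRIB3 ended (adjusted p = 0.0673), without MyoF replicate 5 that of MXI1 (0.210), and without any of the other 10 libraries both ended. Over 30 alternatives, those included, TRIB3 was called in 10 and MXI1 in 11. DESeq2 called 217 genes, 85 higher and 132 lower, these 2 among them.

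Genes of the interferon response had lower values in MyoF. Of 26 tested members 24 were lower, with a median log2 fold change of -1.76, and 19 passed when adjusted over the list alone, against 0 over all genes. ISG15, a ubiquitin-like antiviral protein, was at 4.49 ± 1.27 CPM against 18.7 ± 13.1, and IFI44L at 1.01 ± 0.68 against 13.6 ± 13.5. The list passed camera (adjusted p = 2.38e-17) but not with an estimated correlation (adjusted p = 0.441). Its list mean gave an exact permutation p of 0.0476 before adjustment and 0.759 after, where a pass was almost out of reach. Without the 3 MyoN libraries that had unprefixed codes, the median was -0.36 and camera no longer passed (adjusted p = 0.286). It was -1.48 within set 1 and -2.42 within set 2, and both sets hold such libraries.

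Markers of mesothelium, the lining of the abdominal cavity, and of epithelium were also lower in MyoF by camera, as were complement genes. All 6 mesothelial members tested were lower, with a median of -1.35 (adjusted p = 0.000292, and 0.441 with an estimated correlation), and 2 passed when adjusted over the list alone. MSLN was at 0.701 ± 0.532 CPM against 6.86 ± 5.62, and KRT8, a keratin in both marker lists whose annotated span overlaps KRT18, at 37.9 ± 27.5 against 294 ± 245. Of 7 epithelial members 6 were lower (adjusted p = 0.0461, and 0.596 with an estimated correlation), with 1 passing over the list alone; KRT7 was at 67.1 ± 57.2 against 192 ± 182 CPM. Of 13 complement genes 12 were lower (adjusted p = 0.000335, and 0.561 with an estimated correlation) and 4 passed over the list alone; CD46 was at 115 ± 15.1 against 161 ± 29.2 CPM. With a term for the donor code format none of these 3 lists passed camera (adjusted p between 0.681 and 0.733). Among prefixed donors the mesothelial median was -0.06 over the same 6 members and 0.09 over the 7 that passed the filter there, and the complement median 0.09 over 14, while camera's direction was still lower. KRT8 turned, with a log2 fold change of 0.25.

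Hypoxia response genes were higher in MyoF: 27 of 29 members, with a median log2 fold change of 0.35 (camera adjusted p = 2.56e-08, and 0.441 with an estimated correlation). Of these, 7 passed when adjusted over the list alone and 1, MXI1, over all genes. STC2 was at 463 ± 88.9 against 330 ± 99.3 CPM. The median was 0.44 within set 1, 0.28 within set 2 and 0.34 among prefixed donors. Glycolysis genes were higher in 12 of 20 cases (adjusted p = 0.0219, and 0.659 with an estimated correlation); PFKP was at 366 ± 42.3 against 263 ± 37.2 CPM and ENO2 at 133 ± 39.1 against 78.9 ± 28.4. No glycolysis gene passed over the list alone, and the glycolysis median fell from 0.17 to 0.08 among prefixed donors, where the list did not pass (adjusted p = 0.286).

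Fibrillar collagens and collagen crosslinking enzymes were higher in 19 of 23 cases, with a median of 0.48 (adjusted p = 1.78e-05, and 0.596 with an estimated correlation), though no member passed over the list alone. The collagen median was 0.22 among prefixed donors (adjusted p = 0.0882) and 0.19 with a term for the donor code format (adjusted p = 0.115), and neither passed. COL5A3 was at 25.4 ± 29.1 against 3.85 ± 2.27 CPM and PCOLCE at 157 ± 86.9 against 66.0 ± 61.0. Immediate early and heat shock genes were higher in 19 of 24 (adjusted p = 2.13e-05, and 0.555 with an estimated correlation), and 3 passed over the list alone. Their transcription factors EGR3 and EGR1 were at 12.8 ± 13.8 against 3.596 ± 4.95 and 862 ± 824 against 296 ± 238 CPM. Of 22 unfolded protein response genes 12 were higher (adjusted p = 0.00153, and 0.590 with an estimated correlation), with TRIB3 the 1 that passed; DDIT3, which encodes CHOP, was at 15.3 ± 5.49 against 7.24 ± 2.44 CPM. Smooth muscle contractile genes were higher in 17 of 22 (adjusted p = 0.00928, and 0.659 with an estimated correlation), with 1 higher and 2 lower passing over the list alone. MYOCD, the coactivator myocardin, was at 154 ± 115 against 38.7 ± 17.6 CPM, while the chaperone gene HSPB8 was at 24.0 ± 5.32 against 35.0 ± 8.40.

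Cell proliferation genes were lower in MyoF for all 35 members, with a median of -0.55 (camera adjusted p = 6.95e-08, and 0.659 with an estimated correlation), yet no single member passed over the list alone. MYBL2 was at 20.8 ± 9.13 against 33.6 ± 6.56 CPM and the cyclin gene CCNA2 at 43.1 ± 33.7 against 64.5 ± 29.2. DNA repair genes were lower in 38 of 47 (adjusted p = 0.000733, and 0.596 with an estimated correlation), with RAD51C at 8.23 ± 1.73 against 11.3 ± 1.05 and PARP1 at 41.8 ± 8.53 against 64.4 ± 18.3 CPM. Cholesterol synthesis genes were lower in 21 of 23 (adjusted p = 5.35e-06, and 0.565 with an estimated correlation), with ACAT2 at 8.05 ± 3.05 against 16.1 ± 7.03 CPM. Of 10 HOXA genes 8 were lower (adjusted p = 0.0272, and 0.596 with an estimated correlation); HOXA9 was at 11.8 ± 2.67 against 17.6 ± 4.36 CPM. Ribosomal protein genes were higher in 39 of 41 by a median of 0.17 (adjusted p = 4.11e-06, and 0.659 with an estimated correlation) and mitochondrially encoded genes in 13 of 13 by 0.17 (adjusted p = 0.0219, and 0.708 with an estimated correlation). RPLP1 was at 343 ± 84.3 against 284 ± 82.1, RPS13 at 145 ± 42.4 against 115 ± 12.9, MT-ND2 at 1673 ± 297 against 1399 ± 389 and MT-ND3 at 422 ± 131 against 323 ± 77.1 CPM. The mitochondrial median was -0.13 within set 2, and 0.06 among prefixed donors (adjusted p = 0.677).

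Camera within library set 1 alone passed 13 lists, 10 of them among the 16 above, and within set 2 alone 11 lists, again 10 of the 16. DNA repair, HOXA, epithelial, glycolysis, ribosomal and unfolded protein response genes did not pass within set 1. HOXA, cholesterol synthesis, complement, epithelial, mesothelial and mitochondrially encoded genes did not pass within set 2. The proliferation median was -0.17 within set 1, -0.99 within set 2 and -0.97 among prefixed donors. Among prefixed donors 8 of the 16 lists did not pass, namely interferon, mesothelial, epithelial, complement, collagen, glycolysis, mitochondrially encoded and HOXA genes (adjusted p = 0.0611 for HOXA). With a term for the donor code format 7 did not, the same without HOXA. No list passed among prefixed donors with an estimated correlation.

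The second comparison set fibroid cells against cells of fibroid-free myometrium. No gene passed edgeR's test (smallest adjusted p = 0.279), while 1359 genes had an unadjusted p under 0.05. That count was 312 with a term for the donor code format, and 388 of 14993 genes among prefixed donors. limma voom also called 0 genes, DESeq2 called 181, and edgeR called 1 within set 1 and 3 within set 2. The smallest p belonged to UPK1B, a uroplakin, the membrane proteins of urothelium, at 0.474 ± 0.263 CPM in F against 19.1 ± 14.8 in MyoN. It was followed by CNP at 56.8 ± 5.77 against 77.4 ± 8.89 CPM, APLP1 at 11.7 ± 4.99 against 23.8 ± 10.3, MCTP2 at 0.655 ± 0.555 against 8.82 ± 7.53 and CYBA, a subunit of NADPH oxidase, at 14.1 ± 3.54 against 26.1 ± 3.71. CD44 was at 1353 ± 871 against 1126 ± 381 CPM (adjusted p = 0.928).

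Interferon response genes were lower in F in 24 of 26 cases, by a median log2 fold change of -1.96 (camera adjusted p = 4.11e-23, and 0.441 with an estimated correlation), and 21 passed when adjusted over the list alone. The exact permutation p of the list mean was 0.0159 before adjustment and 0.651 after, and no list mean passed after adjustment in any of the 3 comparisons. The adjustment over 123 tests put a pass almost out of reach, so that outcome carries little weight. ISG15 was at 3.99 ± 1.06 against 18.7 ± 13.1 CPM and IFI6 at 13.3 ± 8.63 against 113 ± 97.1. Among prefixed donors the median was -0.36, and camera still passed (adjusted p = 0.0115), but not with an estimated correlation (adjusted p = 0.834). It was -2.004 within set 1 and -2.10 within set 2.

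**Figure D3:**
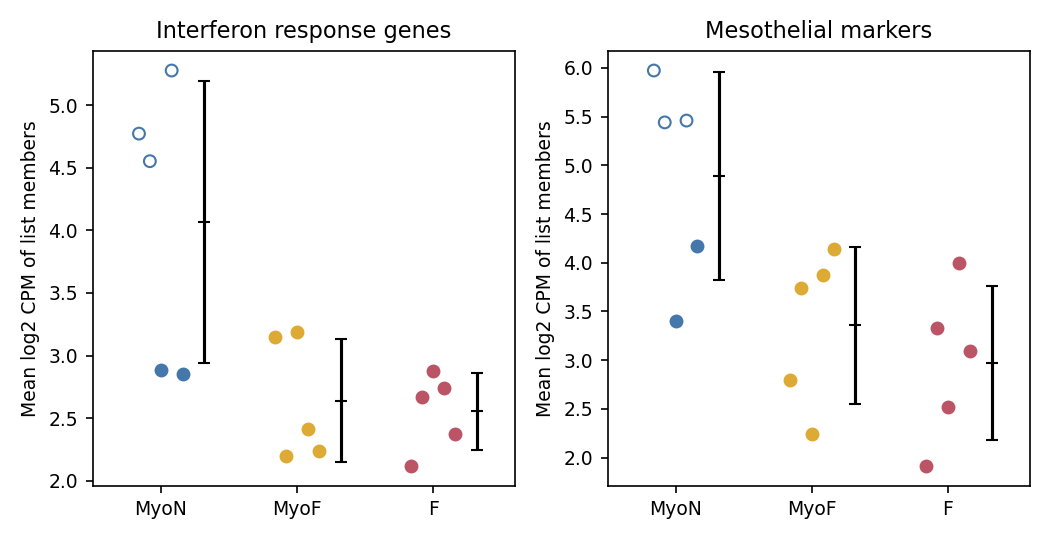
Mean log2 CPM of the tested interferon response genes and mesothelial markers in each library, by group; open points are MyoN libraries with unprefixed donor codes, filled points all others, and bars the group mean with its SD (n = 5). The open points lie above every filled point in both panels.

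The mesothelial markers were lower in F for 6 of 6 members (median -1.99, adjusted p = 2.09e-06, and 0.441 with an estimated correlation), with MSLN at 1.23 ± 1.85 against 6.86 ± 5.62 CPM; 4 passed over the list alone. Epithelial markers were lower for 7 of 7 (adjusted p = 4.53e-05, and 0.441 with an estimated correlation), with KRT8 at 20.96 ± 12.7 against 294 ± 245 and KRT7 at 30.9 ± 17.4 against 192 ± 182 CPM; 3 passed over the list alone. Complement genes were lower for 10 of 13 (adjusted p = 1.41e-05, and 0.441 with an estimated correlation), 8 of them passing over the list alone. SERPING1, the C1 inhibitor, was at 66.0 ± 26.2 against 220 ± 161 CPM and CFI at 0.412 ± 0.249 against 6.49 ± 6.41. With a term for the donor code format the epithelial list still passed camera, and the mesothelial and complement lists did not. The epithelial median moved from -1.47 to -0.42 with that term, and was -0.32 over 10 members among prefixed donors.

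Other lists that passed camera moved by smaller amounts. HOXA genes were lower in 8 of 10 cases (median -0.76, adjusted p = 0.00315, and 0.565 with an estimated correlation), 4 of them passing over the list alone, with HOXA7 at 0.507 ± 0.363 against 1.39 ± 0.803 CPM. The HOXA median was -0.38 among prefixed donors, -0.43 with a term for the donor code format and -0.33 within set 2. Cholesterol synthesis genes were lower in 20 of 23 (adjusted p = 0.00553, and 0.659 with an estimated correlation), with ACAT2 at 10.5 ± 2.68 against 16.1 ± 7.03 and MSMO1 at 35.5 ± 15.6 against 53.03 ± 26.2 CPM. Mitochondrially encoded genes were higher in 13 of 13 by a median of 0.36 (adjusted p = 1.34e-06, and 0.565 with an estimated correlation), with MT-CO2 at 1815 ± 535 against 1365 ± 389 and MT-ATP8 at 511 ± 61.5 against 391 ± 106 CPM. Their median was 0.22 both among prefixed donors and with a term for the donor code format. Immediate early and heat shock genes were higher in 18 of 24 (adjusted p = 0.00129, and 0.565 with an estimated correlation), with 2 higher and 1 lower passing over the list alone. EGR3 was at 11.7 ± 9.89 against 3.596 ± 4.95 CPM and HSPA1B, which shares reads with its near-identical neighbour, at 10.9 ± 2.62 against 17.1 ± 5.09. Hypoxia response genes were higher in 22 of 29 (adjusted p = 0.00977, and 0.596 with an estimated correlation), with 1 higher and 1 lower passing over the list alone; MXI1 was at 94.3 ± 16.9 against 72.6 ± 15.3, whereas the oxygen sensor gene EGLN3 was at 5.91 ± 3.96 against 20.3 ± 12.5 CPM. Of the unfolded protein response genes 15 of 22 were higher (adjusted p = 0.0116, and 0.648 with an estimated correlation), with TRIB3 at 37.9 ± 26.5 against 15.5 ± 5.31 and DDIT3 at 14.1 ± 5.68 against 7.24 ± 2.44 CPM. Fibrillar collagens and collagen crosslinking enzymes were higher in 15 of 23 (adjusted p = 0.0272, and 0.708 with an estimated correlation), with COL14A1 at 7.67 ± 6.12 against 2.16 ± 0.905 and COL5A3 at 13.8 ± 7.02 against 3.85 ± 2.27 CPM, and their median turned from 0.18 to -0.08 among prefixed donors. Within set 1 camera passed 9 of these 11 lists, without the collagen list and the unfolded protein response, and within set 2 it passed 8, without HOXA, cholesterol synthesis and hypoxia genes. Among prefixed donors and with a term for the donor code format it passed 7, without mesothelial, complement, collagen and immediate early and heat shock genes. The immediate early and heat shock median was 0.35, and 0.15 among prefixed donors (adjusted p = 0.0611). Cell proliferation genes, which did not pass over all donors (median -0.12), were lower in F in 34 of 35 cases among prefixed donors (median -0.62, adjusted p = 5.39e-11, and 0.808 with an estimated correlation). Ribosomal protein genes also passed there (median 0.11, adjusted p = 0.00505, and 0.911 with an estimated correlation). Inflammatory cytokines and chemokines, lower over all donors without passing (median -0.29 in F and -0.23 in MyoF against MyoN), were higher among prefixed donors in 26 of 27 cases in both comparisons, with a median of 1.001 in F (adjusted p = 0.000174, and 0.808 with an estimated correlation) and 0.996 in MyoF (adjusted p = 0.00459, and 0.834). All values among prefixed donors rest on 2 MyoN libraries. Over its 24 members tested over all donors, the cytokine list averaged 4.82 log2 CPM in F replicate 1 and 4.94 in MyoF replicate 1. Its means ran from 2.22 to 3.57 in the other F and from 2.22 to 3.34 in the other MyoF libraries. Prefixed MyoN libraries were at 1.96 and 2.90. Both comparisons thus share 1 donor whose values lay above the rest, and the same 2 MyoN libraries.

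The third comparison set fibroid cells against cells of the adjacent myometrium of the same donors. No gene passed edgeR's test (smallest adjusted p = 0.9998), and limma voom and DESeq2 also called 0. In the edgeR fit 310 genes had an unadjusted p under 0.05, where 701 would be expected with no difference. These fits left the donor pairs out. As libraries of a pair deviated together, their p may be too large for this comparison. The median SE was 0.207 in the edgeR fit, against 0.149 with the donor as a block. With that block the number of genes called was again 0, the smallest adjusted p was 0.576, and 1020 genes had an unadjusted p under 0.05. The 5 genes with the smallest p were OGFR at 21.7 ± 3.32 CPM in F against 27.9 ± 6.36 in MyoF, PDZD7 at 0.888 ± 0.229 against 2.18 ± 0.775, ABTB1 at 7.92 ± 2.64 against 11.7 ± 3.69, CERKL at 19.2 ± 5.74 against 11.4 ± 2.06 and RN7SL4P, a pseudogene of the signal recognition particle RNA whose reads are shared with its copies, at 44.4 ± 27.9 against 69.2 ± 50.02. CD44 was at 1353 ± 871 against 1059 ± 540 CPM.

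Hypoxia response genes were lower in F for 29 of 29 members by a median log2 fold change of -0.17 (camera adjusted p = 1.78e-05, and 0.441 with an estimated correlation), and the list mean was lower in F in 5 of 5 donor pairs (exact permutation p = 0.0625, the smallest the pairs allow). VEGFA, the angiogenic growth factor, was at 455 ± 137 against 661 ± 192 CPM and MXI1 at 94.3 ± 16.9 against 123 ± 20.6. The list of fibrillar collagens and collagen crosslinking enzymes was lower in 19 of 23 members (adjusted p = 0.00359, and 0.659 with an estimated correlation) and in all 5 pairs. Its enzyme genes PLOD1 and P4HA2 were at 784 ± 138 against 981 ± 302 and 272 ± 44.4 against 335 ± 87.6 CPM. Epithelial markers were lower in 7 of 7 (adjusted p = 0.0116, and 0.565 with an estimated correlation) and likewise in all 5 pairs. MUC1 was at 23.9 ± 10.5 against 31.96 ± 7.32 and KRT19 at 92.6 ± 65.4 against 174 ± 94.2 CPM. The pair p is not adjusted for the 41 lists tested, and some of these would agree in all 5 pairs by chance. Immediate early and heat shock genes were also lower in all 5 pairs, without passing camera in the main fit (adjusted p = 0.189).

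Cell proliferation genes were higher in F for 35 of 35 members by a median of 0.40 (camera adjusted p = 1.30e-11, and 0.596 with an estimated correlation). Their list mean was higher in F in 3 of 5 pairs (exact permutation p = 0.312), so that the sign did not hold in each donor. MCM6 was at 35.5 ± 13.4 against 27.5 ± 8.20 and CCNA2 at 63.7 ± 33.1 against 43.1 ± 33.7 CPM. DNA repair genes were higher in 39 of 47 (adjusted p = 4.90e-07, and 0.555 with an estimated correlation) and in 4 of 5 pairs, with RAD51B at 3.84 ± 0.23 against 2.56 ± 0.512 and ATR at 37.7 ± 9.99 against 29.8 ± 9.31 CPM. Without the donor block no member of any list passed over the list alone in this comparison, and with it members of 6 lists did, among them 3 hypoxia response genes, all lower in F. The proliferation median was 0.54 within set 1 and 0.12 within set 2, where the list did not pass (adjusted p = 0.157).

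**Figure D4:**
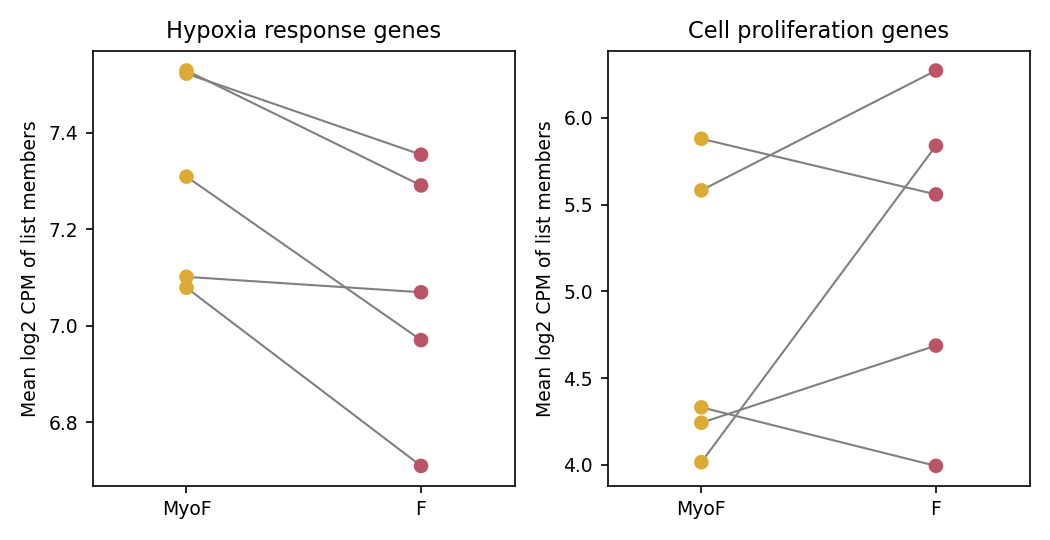
Mean log2 CPM of hypoxia response genes and cell proliferation genes in MyoF and F, with a line joining the 2 libraries of a donor (5 pairs). The hypoxia mean was lower in F in 5 of 5 pairs, and the proliferation mean was higher in F in 3 of 5.

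Smooth muscle contractile genes were lower in F in 21 of 22 cases (adjusted p = 0.000513, and 0.596 with an estimated correlation), with TPM2 at 699 ± 469 against 905 ± 543 and SYNM at 12.0 ± 2.19 against 15.6 ± 2.56 CPM. Matrix glycoproteins were lower in 25 of 30 (adjusted p = 0.0312, and 0.659 with an estimated correlation), with MFAP4 at 38.7 ± 21.9 against 60.5 ± 37.6 and FMOD at 5.42 ± 2.74 against 8.71 ± 3.502 CPM. Basement membrane genes were lower in 15 of 19 (adjusted p = 0.0386, and 0.565 with an estimated correlation), with AGRN at 106 ± 45.6 against 155 ± 81.6 and LAMB2 at 315 ± 76.3 against 398 ± 120 CPM. Ribosomal protein genes were lower in 41 of 41 by a median of -0.17 (adjusted p = 2.17e-10, and 0.596 with an estimated correlation); RPLP1 was at 300.3 ± 78.7 against 343 ± 84.3 and RPL3 at 619 ± 207 against 743 ± 278 CPM. Mitochondrially encoded genes were higher in 13 of 13 (adjusted p = 0.00346, and 0.659 with an estimated correlation), with MT-CO2 at 1815 ± 535 against 1547 ± 676 and MT-ND4L at 488 ± 85.2 against 427 ± 75.4 CPM. Cholesterol synthesis genes were higher in 19 of 23 (adjusted p = 0.0136, and 0.680 with an estimated correlation), with IDI1 at 29.5 ± 16.1 against 22.5 ± 7.84 CPM. Within set 1 camera passed 8 of these 11 lists and within set 2 it passed 4, the hypoxia, ribosomal, collagen and mitochondrial ones. The mitochondrial median was -0.04 within set 1. With the donor as a block all 11 passed, and so did HOXB genes, lower in 7 of 7 (adjusted p = 0.0223, against 0.0722 without the block), and immediate early and heat shock genes, lower in 18 of 24 (adjusted p = 0.00379, against 0.189). With an estimated correlation no list passed in the fit with the block (smallest adjusted p = 0.489). The list means were higher in F in 1 of 5 donor pairs for contractile, basement membrane and ribosomal protein genes, in 2 of 5 for matrix glycoproteins, in 3 of 5 for cholesterol synthesis genes and in 4 of 5 for mitochondrially encoded genes.

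Across genes, which are not independent replicates, the log2 fold changes of MyoF and of F against MyoN had a Pearson correlation of 0.86 and a covariance of 0.205. Both comparisons share the MyoN libraries, and simulated unchanged groups against shared controls gave a correlation of 0.49 and a covariance of 0.057. With the MyoN libraries divided between the comparisons the correlation averaged 0.39 over 20 divisions, and the covariance 0.119. F and MyoF also share donors, and with the donor pairs divided too the correlation averaged 0.17 over 60 divisions, from -0.39 to 0.45, and the covariance 0.0595. The simulated values are for shared controls and are no reference for these divided ones. The correlation was 0.84 within set 1, 0.77 within set 2 and 0.79 among prefixed donors. In each of these fits both comparisons share fewer MyoN libraries than in the main fit, and F and MyoF still share donors. No simulated reference was made for these fits, and 0.49 is none for them. The value among prefixed donors therefore does not show whether the fold changes go together without the unprefixed donors.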

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

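Within groups of 5 libraries, a value was picked out here when its gap to the nearest other value was over 0.71 of the group's range. Of 264 groups of values tested 17 met this, and about 13.2 would by chance alone, so single cases carry little weight. No explanation was tested for them.

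CD44, the sort antigen, reached 2910 CPM in 1 F library, against 913 to 1060 in the others. EGR3, an immediate early gene, had a library apart in each group: 29.2 CPM in F against 5.35 to 8.82, 36.8 in MyoF against 4.54 to 12.2, and 12.4 in MyoN against 0.747 to 1.96. Among matrix genes, COL5A3 reached 77.3 CPM in MyoF against 9.64 to 15.1 in the others. COL6A2 reached 1410 CPM in MyoN against 402 to 603, and FMOD 30.1 CPM in MyoN against 7.11 to 12.4. The mean log2 CPM of basement membrane genes reached 7.47 in MyoN, against 6.60 to 6.85.

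Of complement genes, CFI reached 2.72 CPM in MyoF, against 0.437 or less in the others, and SERPING1 reached 111 CPM in F against 42.4 to 59.8. MSLN reached 4.50 CPM in F against 0.104 to 0.877, UPK1B 0.937 CPM in F against 0.277 to 0.404, and MCTP2 1.75 CPM in MyoF against 0.465 to 0.688. The remaining values lay below the rest instead. MT-ATP8 was at 404 CPM in 1 F library against 521 to 559, and MT-ND3 at 318 CPM against 445 to 488. MYBL2 was at 22.0 CPM in 1 MyoN library against 35.5 to 38.4, and the mean log2 CPM of epithelial markers was 1.96 in 1 F library against 3.90 to 4.63.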

How the results depend on the processing

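The term for the donor code format, the fits on prefixed donors, the sample weights, the permutation of list means, the donor pair divisions and the lists with a library left out were chosen after the data were seen. For MyoF against MyoN the count of 2 genes became 0 with RLE scaling, without the set term, with only the 2 groups, with donor correlation in limma voom, with the code term and with prefixed donors. It became 1 in set 1, 1 with a 2-fold minimum, 4 with sample weights, 217 with DESeq2 and 1241 with no low-count filter. For F against MyoN the count of 0 became 1 in set 1, 3 in set 2, 181 with DESeq2 and 1164 with no filter, and for F against MyoF 109 with no filter. Of the unfiltered calls 1044, 972 and 97 were among the 14024 filtered genes. Keeping the low-count genes changed the fit for these too: without the filter their median prior degrees of freedom were infinite, against 2.63, and the highest quasi-likelihood dispersion 0.836 against 53.9. The cause of the other changes was not tested.

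Leaving out 1 library gave 0 to 22 genes for MyoF against MyoN, 0 to 18 for F against MyoN and 0 for F against MyoF. The first count was 22 without MyoN replicate 3, 10 without MyoN replicate 5, 2 without F replicate 1, and 0 or 1 without any other; the second was 18 without MyoN replicate 3. MyoN replicates 3 and 5 are the MyoN libraries with prefixed donor codes. With an unprefixed MyoN library left out (replicate 1, 2 or 4) the first count was 0 each time. The direction of TRIB3 and MXI1 held in each alternative.

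Lists called fell to 0 in each comparison with an estimated correlation, and for MyoF against MyoN to 10 with the code term and 9 with prefixed donors. The replicate block gave 0 genes and 13 lists for F against MyoF and ended no call. The fold-change correlation moved to 0.39 with MyoN libraries divided and 0.17 with donor pairs divided too.

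Among the genes reported, directions turned for CD44, whose log2 fold change was never called: 0.23 in set 1 for MyoF against MyoN; -0.45 in set 2, -0.0556 with the code term, -0.0847 with prefixed donors and -0.0843 with weights for F against MyoN; and -0.0288 with weights for F against MyoF. With 1 library left out CD44 ran from -0.44 to 0.12, from -0.23 to 0.46 and from -0.16 to 0.73. For MyoF against MyoN, KRT8 was 0.26 with the code term and 0.25 with prefixed donors, and in set 2 MT-ND3 was -0.34 and the mitochondrial list -0.13. For F against MyoN the collagen list was -0.12 with the code term and -0.0822 with prefixed donors. For F against MyoF the mitochondrial list was -0.0429 in set 1, and in set 2 MCM6 was -0.0420 and the cholesterol list -0.0080. Medians of MyoF against MyoN also crossed 0 while camera's direction held, without a call: complement genes at 0.00092 with the code term and 0.0862 with prefixed donors, mesothelial markers at 0.0926 with prefixed donors (7 members tested there, and -0.0640 over the 6 tested over all donors), and unfolded protein response genes at -0.0182 in set 1. Of the other values for single genes, 2416 kept direction and side of the threshold, 72 gained a call and 39 lost one. Nearly all of the 2416 are of genes that were not called and stayed so. Only TRIB3 and MXI1 had a call to lose: of 30 values each, 10 and 11 kept it. For lists 702 kept direction and call and 194 lost the call, 38 of these with an estimated correlation and 38 with the permutation of list means. Depth limits genes of few counts: the shallowest library had 5143548 counts.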

Other observations

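The tests on the donor code format and on mesothelial cells, and the correlations with set means removed, were chosen after the result was seen. Several groups of genes tied to fibroid biology did not pass camera. Of 19 tested genes often raised in fibroid tissue, 12 were higher in F than in MyoF (adjusted p = 0.118) and 13 higher in F than in MyoN (adjusted p = 0.289). Steroid hormone receptors and targets were higher in F than in MyoF in 10 of 18 cases (adjusted p = 0.947), WNT pathway genes in 11 of 22 (adjusted p = 0.995) and TGF-beta and activin genes in 11 of 27 (adjusted p = 0.785). Mesenchymal stem cell surface markers did not pass in any comparison (adjusted p = 0.715, 0.416 and 0.627), nor did pluripotency genes (adjusted p = 0.785, 0.785 and 0.997).

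The 3 MyoN libraries with unprefixed donor codes differed from the 2 prefixed MyoN libraries in the fit with a term for the code format. That term called 39 genes, 29 higher and 10 lower. Since every MyoF and F donor is prefixed, it compares MyoN libraries only. Interferon genes were higher in the unprefixed libraries in 26 of 26 cases (camera adjusted p = 6.75e-30, and 0.0653 with an estimated correlation). Inflammatory cytokines and chemokines were higher in 20 of 24 (adjusted p = 2.64e-05, and 0.586 with an estimated correlation), while proliferation genes were higher in 1 of 35 (adjusted p = 9.77e-07, and 0.904 with an estimated correlation).

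The first pattern is the lower interferon genes in MyoF and F than in MyoN. Depth was looked at by thinning each library at random to the lowest total. Such thinning leaves expected fold changes nearly unchanged whatever the cause, so it cannot decide on depth. The F median was then -1.96. Among prefixed donors it was -0.356, so most of the difference may follow the donors of the unprefixed format, 3 of the 5 MyoN donors; what that format stands for, and whether handling or the donors themselves differ with it, was not tested. Over 10 donors with group means removed, interferon and mesothelial means had a Pearson r of 0.626 (permutation p = 0.0556, adjusted 0.111 over 2 correlations) and a Spearman rho of 0.552 (permutation p = 0.103, adjusted 0.206). Without the 2 donors farthest from the median r was 0.490, and with set means removed too it was 0.669. Removing group means leaves the split of MyoN donors by code format in. Both lists had already been seen to be higher in the unprefixed ones, so a positive r was likely beforehand. For this reason, and with so few donors, mesothelial cells as a source cannot be told apart from other donor differences.

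The second pattern is the lower mesothelial markers. The F median was -1.94 after thinning, which likewise cannot decide on depth, and -0.397 among prefixed donors, so it too may follow the unprefixed donors. Of the 6 tested members 83.3% were higher in unprefixed MyoN libraries, with KRT8 at 469 and KRT18 at 619 CPM there, against 30.97 and 301 in prefixed MyoN. Whether mesothelial cells passed the sort, or the cultured cells themselves expressed these genes, cannot be told apart, since 2 of the 6 are also epithelial markers and the test used genes of the pattern itself.

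The third pattern is lower hypoxia and higher proliferation genes in F than in MyoF. After thinning the hypoxia median was -0.127, against -0.170 before, which again cannot decide on depth. A shared culture state, such as density, would set the lists against each other. Over 10 donors with group means removed they had a Pearson r of -0.231 (permutation p = 0.510, adjusted 0.510) and a Spearman rho of -0.188 (permutation p = 0.608, adjusted 0.608), r was -0.478 without 2 donors, and with set means removed too it was 0.608. The sign thus depends on the library sets, and averaging F with MyoF leaves out the contrast itself, so a shared culture state cannot be told apart from other causes. A difference between fibroid and adjacent tissue stays open, as untested.

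Other splits of the same libraries into groups of 5 were tested, 100 in each comparison with the real one. For MyoF against MyoN 3 splits called at least the 2 genes found (highest other 10), so over these splits chance is excluded at 0.05 for that count. All 3 are among the 17 splits that keep the unprefixed donors together, and within those chance is not excluded. For lists 7 splits gave 16 or more (highest other 20), and chance is not excluded. For F against MyoN 48 splits gave at least 11 lists (highest other 18) and for F against MyoF 33 gave at least 11 (highest other 16), so chance is not excluded for the lists of either comparison. Their real gene counts are 0, which each of the 100 splits reaches, so those counts test nothing; another split called 107 genes for F against MyoN, which points to a structure of the samples, and at most 1 for F against MyoF. Of the 16 splits that part all 5 pairs, the real one included, the others gave at most 10 lists against the real 11. These splits are too few for a share under 0.05. With DESeq2 only 20 splits were taken, the real one included, which is too few for a share under 0.05. Another split called 436 genes against the real 217 for MyoF against MyoN, and 758 against 181 for F against MyoN. No conclusion on chance is drawn from these.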
